A study of Corynebacterium glutamicum R with 4 samples.

How the data were processed

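RNA of 4 cultures of C. glutamicum R was compared before and after IPTG on 4 arrays. Per the labels' protocols, cultures were grown in 100 ml of nutrient rich medium with 1% glucose at 33 °C in 500 ml flasks, and cDNA made from 10 μg of total RNA was labelled indirectly with Cy3 or Cy5. Per the labels, Cy3 held the RNA before induction and Cy5 the RNA after 15 min on every array, so log2(Cy5/Cy3) was read as the change after IPTG. Arrays were grouped by title and plasmid label. On the vector array the source name of channel 2 describes the sigC plasmid strain, while its title and the plasmid label of both channels name the empty vector. It was treated as the vector control, and the values were not used to settle this.

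The scanner files deposited by the authors hold spot intensities in Cy3 and Cy5, as median signals, median local backgrounds and background-subtracted signals, before normalization. Per the file headers they were made with Agilent Feature Extraction 10.5.1.1, while the submitters' processing notes name version 10.5.5.1. The files also hold the software's log10 ratio of Cy5 over Cy3, normalized by the software per the file headers. The authors' value table of the series holds log2 ratios, with a scale and direction not stated in it. Set against the scanner log ratios converted to log2, its columns gave slopes from 0.989 to 1.01 and correlations from 0.978 to 0.998. This makes it a log2 ratio in the same direction. The medians of its columns were -0.0095, -0.0070, -0.0143 and -0.0142. Those of the scanner log ratios, which the software had normalized, were also near 0, at 0.0100, -0.0048, -0.0240 and -0.0092. Whether the table had a further step is not given in the sources used here.

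Each array had 6864 spots, of which 308 were control spots, 302 of them empty, and 3278 measuring probes with 2 spots each. Background was corrected with normexp and an offset of 50, fitted on all spots, and each array was normalized by loess with control spots at weight 0. The plan named mean signals, but the files hold medians, which were used instead. Spots carrying the software's outlier flags were removed (31, 141, 161 and 78 on sigC arrays 1 to 3 and the vector array), and the 2 spots of a probe were averaged. The SD of log2 ratios between duplicate spots was 0.09, 0.18, 0.18 and 0.10. Probes were kept when well above background in at least 1 channel on at least 2 of the 4 arrays, with values on at least 2 sigC arrays and the vector array. This left 3159 probes, with 116 dropped as dim and 3 for missing values.

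Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes on log2 ratios and a mean per strain. Before and after RNA were thus paired on the array. The first contrast set the mean of the 3 sigC arrays against 0, and the second set it against the vector array. The spread came from the sigC arrays alone, with 2 residual degrees of freedom and 8.03 prior ones. P values were adjusted by the Benjamini-Hochberg method over all tested probes, with a threshold of 0.05. The first contrast includes any effect of IPTG, of 15 min of growth and of a probe's dye preference. Channel levels were taken after loess and Aquantile normalization between arrays, and they are open to dye bias. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

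The steps were tested on simulated data with 200 changed probes among 3159. For the first contrast 98% of changes of 0.5 on the log2 scale and 100% of those of 1, 2 and 4 were recovered, with 3 false calls. For the second contrast 24%, 94%, 100% and 100% were recovered, with 2 false calls. The simulated probes shared the spread model of the fit, so these shares do not cover a spread that grows with the size of a change.

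The rule for named items, set before the data were examined, was based on gene lists and the largest changes. Because the files do not pair probes with genes, the lists, their set tests, the sigC value and the count of neighbouring genes were not run. The reference table at hand describes another strain with no link to these probes and was not used. From the part on largest changes, 2 rises and 2 falls are named: the 2 largest rises, which were the same in both contrasts, and the largest fall of each contrast. The alternatives covered background correction, normalization, the filter, variance moderation, pairing of the channels, the source of the values, each left-out sigC array and a fold limit. The block of the software setting, the 8-fold limit and a threshold of 0.1 were added after seeing the data.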

Results

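Transcript levels were measured with 2-colour Agilent arrays in the wild type of Corynebacterium glutamicum R, a Gram-positive soil bacterium used for amino acid production. The strain carried either a plasmid for IPTG-induced expression of sigC (pCRC634) or the empty vector (pCRB12iP). The gene sigC encodes a sigma factor of the extracytoplasmic function family, a subunit that directs RNA polymerase to a set of promoters, and IPTG is a synthetic inducer of lac-type promoters. Each array compared RNA taken before induction, labelled with Cy3, with RNA taken 15 min after 0.5 mM IPTG was added, labelled with Cy5. There were 3 arrays of the sigC plasmid strain, which the series design describes as independent experiments, and 1 array of the vector strain. The dyes were never swapped. The median spot signal in Cy3 and Cy5 was 809 and 1440.5 on sigC array 1, 2089 and 3328 on array 2, 1504 and 3002 on array 3, and 2530 and 4595 on the vector array. The median local background was between 130 and 186, and no spot was saturated. The array held 3278 measuring probes with 2 spots each, and 3159 were tested. Precision was limited by the number of arrays. The files used here do not pair probes with genes, so probes are given by identifier, no more than 2 per direction. The probe for sigC itself is not named, so whether a named riser measured the overexpressed sigC is not known.

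The first comparison asked which transcripts differed between the time before induction and 15 min after it in the sigC plasmid strain. On its own it does not separate sigC from IPTG, 15 min of growth or a probe's dye preference. After induction 652 probes rose and 542 fell, together 37.8% of those tested. Most of these changes were small, with a median size of 0.42 on the log2 scale, and 1151 of the 1194 lay under 2-fold. At least 2-fold changes were seen for 43 probes, of which 31 rose and 12 fell, and all 43 had the same sign on the 3 sigC arrays. A group of 13 probes rose at least 8-fold, a limit set after the values were seen, with a median log2 change of 3.78. No probe fell that far, and the 12 that fell at least 2-fold ranged from -1.07 to -2.15.

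The largest rise was that of probe ID_347, between 6.71 and 7.61 on the 3 arrays. Its mean log2 change was 7.10 ± 0.46 (SD, n = 3), or 138-fold, with a limma adjusted p of 9.7e-10. Probe ID_2376 came next at 4.96 ± 1.45 (SD, n = 3), or 31.1-fold, with a limma adjusted p of 3.3e-05. Its 3 values were 4.05, 4.20 and 6.63, so that array 3 set most of its spread. The largest fall was that of probe ID_1444, whose mean log2 change was -2.15 ± 0.19 (SD, n = 3), a signal 4.43-fold lower after induction (limma adjusted p = 1.4e-06, or 0.062 with unpaired channels). Probe ID_1030 fell by 1.38 on the log2 scale (SD 0.12, n = 3), or 2.59-fold, with a limma adjusted p of 1.2e-05. All 13 probes of the strongest group had higher ratios on array 3 than on both other arrays, with a median of 5.38 there against 3.17 on array 1 and 2.98 on array 2.

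These calls are from limma with Benjamini-Hochberg adjustment at 0.05, and 1502 probes had an unadjusted p under 0.05. Treating the channels as separate, unpaired samples lowered the count from 1194 to 30. The 31 risers of at least 2-fold became 61 with the scanner software's log ratios, 64 with the authors' value table, 19 with an intensity trend and robust prior, and 16 with unpaired channels. The robust prior called 3 of the 13 strongest risers, whereas without array 3 all 13 were called but 7 reached 8-fold.

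**Figure D1:**
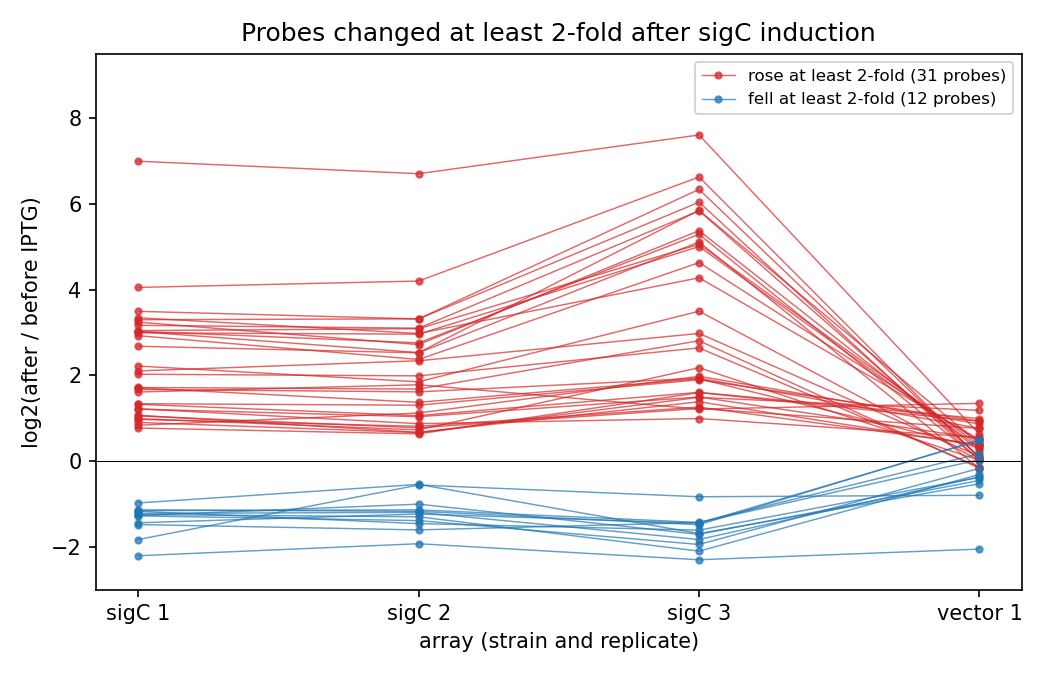
Log2 ratio of the signal after IPTG to that before it, for each probe that changed at least 2-fold in the sigC plasmid strain, on the 3 sigC arrays and the vector array. Each line joins the values of 1 probe, with 31 risers in red and 12 fallers in blue, and the strongest risers lie higher on array 3 than on arrays 1 and 2 and near 0 on the vector array.

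The vector strain received IPTG as well, and on its array Cy3 and Cy5 again held the RNA before and after it. By title and plasmid label this strain carried the empty vector, though the source name of channel 2 describes the sigC plasmid strain. Its array shared the setting of the scanner software with sigC array 3 but not with arrays 1 and 2. It is a single array, so its values have no replicate check and were not tested alone. On it 14 probes had a ratio at least 2-fold up and 3 at least 2-fold down. The 13 strongest risers of the sigC strain had vector ratios between -0.18 and 0.62 on the log2 scale. For the 18 probes that rose between 2- and 8-fold, the median log2 change was 1.32 in the sigC strain and 0.54 on the vector array, and 10 of them had a vector ratio of at least 0.5. Probe ID_1444 had a log2 ratio of -2.06 on the vector array. Of the 1194 probes that changed in the sigC strain, 1124 had a vector ratio of the same sign (94.1%), against 70.4% of the probes without a call. A call favours larger changes, whose sign is less open to noise, so the gap between these shares is partly built in. The mean of the sigC arrays correlated with the vector array across probes at r = 0.599 (Spearman rho = 0.767), where probes are not independent replicates. Pearson's r was 0.802, 0.821 and 0.862 between sigC arrays 1 and 2, 1 and 3, and 2 and 3, and 0.528, 0.601 and 0.567 between arrays 1, 2 and 3 and the vector array. Spearman's rho did not separate the strains in this way, with 0.690, 0.728 and 0.779 between the same sigC pairs and 0.630, 0.698 and 0.752 with the vector array.

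**Figure D2:**
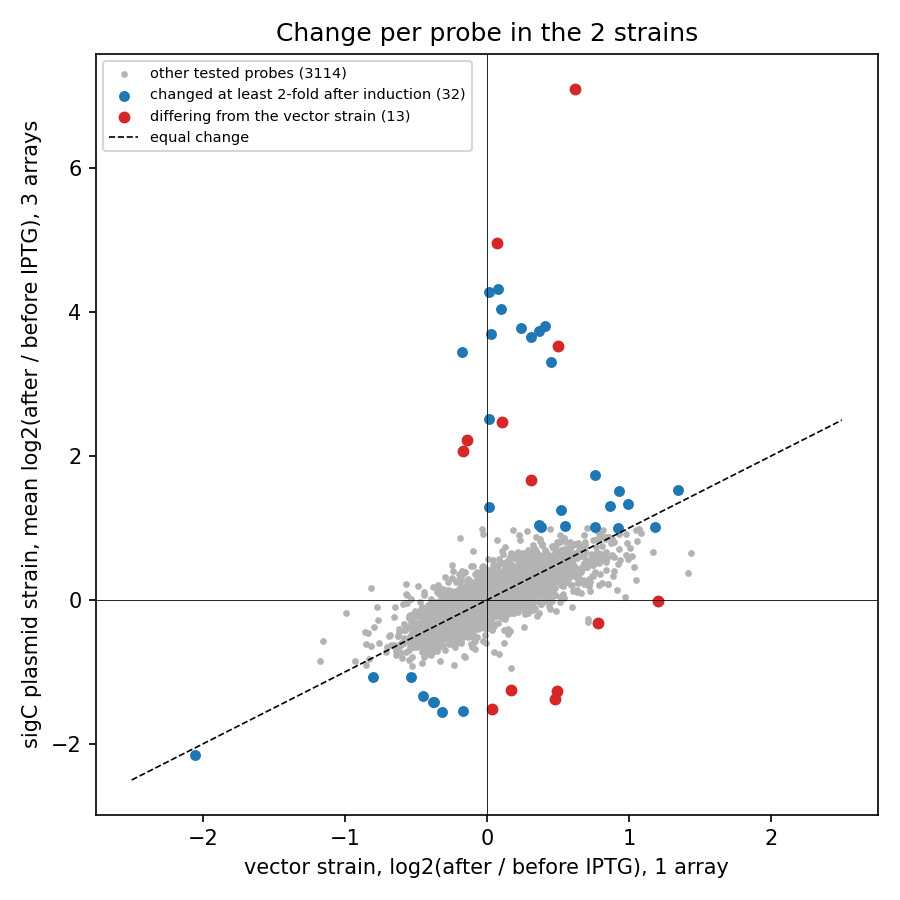
Mean log2 ratio after to before IPTG over the 3 sigC arrays (vertical axis) against the log2 ratio on the vector array (horizontal axis), 1 point per tested probe. Blue points are probes that changed at least 2-fold in the sigC strain without a tested difference from the vector strain, red points are the 13 probes with one, and the dashed line marks equal change. The grey points follow the dashed line, while the strongest risers stand above it at vector ratios between -0.18 and 0.62.

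The second comparison asked which changes in the sigC strain went beyond those of the vector strain. It found 13 probes, of which 7 rose more after IPTG in the sigC strain, by 1.36 to 6.48 on the log2 scale. The other 6 had lower ratios in the sigC strain, with differences from -1.10 to -1.86. Of these 6 probes, 5 had ratios below 0 on every sigC array and above 0 on the vector array. Among the 13 probes, 12 had also changed in the first comparison and in the same direction, an overlap that is partly built in because both comparisons use the same 3 sigC arrays.

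The difference between strains was 6.48 for ID_347 (SE 0.29, limma adjusted p = 2.4e-06) and 4.89 for ID_2376 (SE 0.77, limma adjusted p = 0.025). Probe ID_1030 had the largest difference in the other direction, at -1.86 (SE 0.18, limma adjusted p = 0.0020), with a log2 ratio of 0.48 on the vector array. For ID_1444 the difference was -0.09 (limma adjusted p = 0.99), and its sign turned to 0.25 when arrays were scaled to equal spread. Of the 13 probes that rose at least 8-fold in the first comparison, 3 passed this test. The other 10 had differences of at least 2.86 on the log2 scale but limma adjusted p values between 0.055 and 0.32. Of the 18 weaker risers 4 passed, and of the 12 fallers 4 passed.

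This contrast sets 3 arrays against 1 and assumes that the vector array varies like the sigC arrays, and 169 probes had an unadjusted p under 0.05. The count moved from 13 to 17 without sigC array 1, to 34 without array 2 and to 50 without array 3. Of the 13 strongest risers, 4 passed without array 1, 13 without array 2 and 13 without array 3. Each left-out fit had fewer residual degrees of freedom and leaned more on the prior, so these counts do not show which array mattered. The scanner software's log ratios gave 3, unpaired channels gave 1, as did the authors' value table, no background correction gave 20, no filter on dim probes 20 and scaling between arrays 33. ID_2376 missed the threshold with the scanner log ratios (limma adjusted p = 0.34), the value table (0.24), median centring (0.052), the robust prior (0.99) and unpaired channels (1.00). ID_1030 missed it with the value table (0.056) and unpaired channels (0.37). Arrays 1 and 2 shared 1 setting of the scanner software, and array 3 and the vector array shared another. With that setting as a block, chosen after seeing the data, the contrast became array 3 minus the vector array. Its spread came from arrays 1 and 2 alone. The difference was then 6.99 for ID_347, 6.56 for ID_2376 and -1.93 for ID_1030. The second setting held 1 array of each strain, which allows no test within it, and the first held sigC arrays only.

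**Figure D3:**
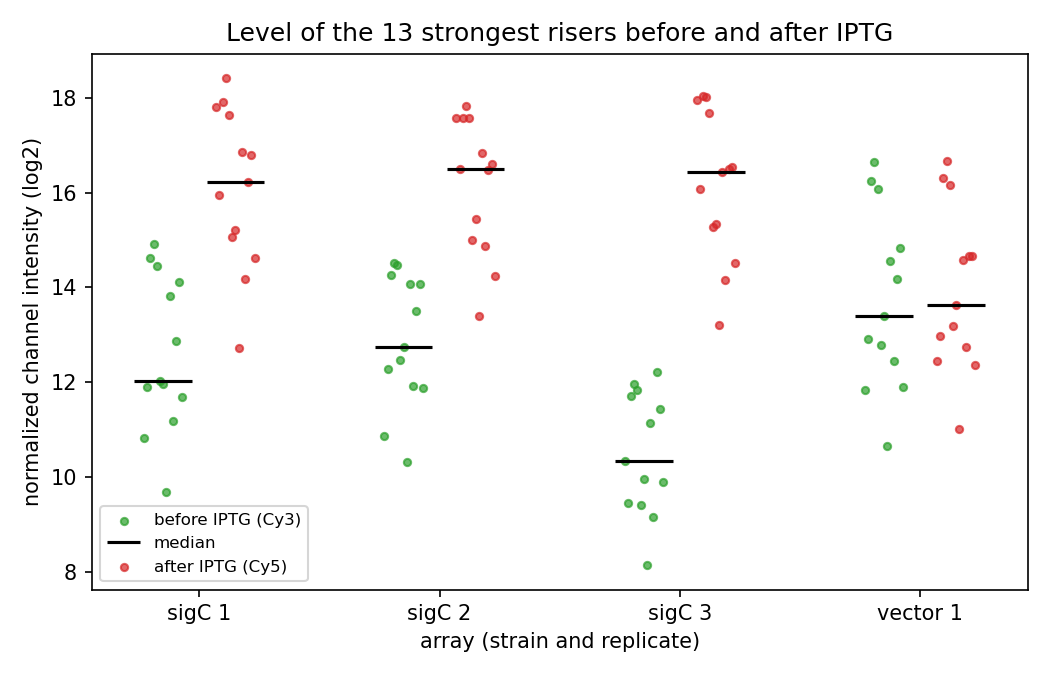
Normalized log2 channel intensity of the 13 probes that rose at least 8-fold, before IPTG (Cy3, green) and after it (Cy5, red), on the 3 sigC arrays and the vector array. Each point is 1 probe and each bar the median, which before IPTG was 12.03, 12.73 and 10.35 on the sigC arrays and 13.39 on the vector array, and after IPTG 16.22, 16.49, 16.44 and 13.63.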

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

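The test of the level before induction in culture 3 and that of dye bias were chosen after the results were seen. The change after IPTG differed between the sigC and the vector strain for 13 probes by the limma contrast. Probe ID_347 differed by 6.48 on the log2 scale, ID_2376 by 4.89 and ID_1030 by -1.86. In ID_1030 the 3 sigC arrays fell and the vector array lay at 0.48.

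The 13 strongest risers had log2 ratios on sigC array 3 that were 1.77 times the mean of arrays 1 and 2 (median, quartiles 1.65 and 1.86). In the second comparison 3 of them passed, 13 without array 2, 13 without array 3 and 4 without array 1. The left-out fits leaned more on the prior, so these counts do not single out an array. Signals near background on arrays 1 and 2 are argued against, since the median Cy3 signal there was 29.4 times the local background (10.7 on array 1, 37.2 on array 2, and 5.66 on array 3, where the lowest was 1.46). A stretch of all ratios on array 3 stays open by the limit set before the values were seen. The same quotient over the other 1181 called probes had a median of 1.23, and its 95% interval of 1.20 to 1.27 includes that limit. This interval treats probes as independent. The quartiles of these other probes, 0.91 and 1.63, lay below the risers' lower quartile, so a stretch by 1 shared factor would not reach the risers' quotient. By channel, the normalized Cy3 level of the risers on array 3 lay at -2.63 against arrays 1 and 2 (quartiles -2.73 and -1.90). The Cy5 level lay at 0.07, so the larger ratio lay in Cy3, the channel of the RNA before induction. Over all tested probes the same Cy3 difference had an SD of 0.345, so the channel as a whole did not shift like the risers. Normalization would have removed a shift common to all probes. With 1 array, a lower level in culture 3 cannot be told apart from a difference in how that channel was measured for these probes. A lower level before induction in culture 3 thus stays open too. The recorded difference of array 3 from arrays 1 and 2 is the scanner software's setting, which it shares with the vector array and which was not tested as a cause here.

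The ratios of the sigC and vector arrays moved together for most probes. An intensity trend left after loess is argued against, since the correlation within 20 intensity bins was 0.598, close to the 0.599 without bins. Dye preference of single probes cannot be told apart from a shared response to IPTG or to 15 min of growth. Without the probes changed at least 2-fold the correlation was 0.762, and either could give it, since no array had the dyes swapped.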

How the results depend on the processing

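The block of the scanner software's setting, the 8-fold limit and the threshold of 0.1 were chosen after seeing the data. Of the named values, all kept their sign under every alternative run except the strain difference of ID_1444, which turned from -0.09 to 0.25 with scaling between arrays and passed no test in either. Of the probes called in the sigC strain both ways, 1 had the opposite sign under median centring. The count of changed probes stayed between 1098 and 1349 for background correction, normalization, filter, moderation and source of values, and between 894 and 1002 when 1 sigC array was left out. It was 30 with separate channels and no replicate block, where differences between cultures enter the spread, and 43 with a 2-fold limit. Risers of at least 2-fold numbered 61 with the scanner log ratios, 64 with the authors' value table, 19 with the intensity trend and robust prior, 16 with separate channels and 26 to 43 with an array left out. The 8-fold risers numbered 3 with the robust prior, 9 with separate channels and 7 to 13 with an array left out. Fallers of at least 2-fold numbered 10, 8 and 12 to 14 under the same alternatives. Beyond the vector strain, 3 probes passed with the scanner log ratios, 1 with the value table, 1 with separate channels, 20 without background correction, 20 without a filter, 33 with scaling between arrays, 57 with the software setting as a block (1 residual degree of freedom), 31 at a threshold of 0.1 and 17 to 50 with an array left out (50 without array 3). The robust prior gave 13, of which 9 were the same probes. Apart from the 2-fold limit and the threshold, the cause was not tested. With an array left out the fit also leaned more on the prior, so those counts do not show which array made the difference. No paired analysis was possible across strains because the vector strain had 1 array; slide and scan date were not run as blocks, since each slide held 1 array and all were scanned on 1 day, nor was the median of several probes, since each identifier had 1 probe. Gene list tests and the sigC value were not run for want of gene names. Signal over background was lowest on sigC array 1, where 2860 probes were well above background in Cy3 against 3126 on the vector array.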

Other observations

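The test of probe pairs with consecutive identifier numbers and the comparison of levels before induction were chosen after the results were seen. Before induction the 13 strongest risers were higher in the vector strain than on any sigC array. The median difference was 1.62 on the log2 scale from the mean of the sigC arrays (range 0.75 to 2.85) and 0.65 from the highest of them, with a smallest margin of 0.03. After induction all 13 were higher on each sigC array than on the vector array, with a median difference of 1.92 for the mean of the sigC arrays and 1.70 for the lowest of them. Across all tested probes, 23.7% had their highest level before induction on the vector array. Some of the 13 had consecutive identifier numbers, and such probes tended to change together, so the 13 are not independent observations. The vector levels came from 1 array. The risers were picked by their ratios, which favours low levels before induction on the sigC arrays. In limma's unpaired fit of the channels none of the 3159 probes passed the adjusted test for this difference, while 133 had an unadjusted p under 0.05, among them 5 of the 13.

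Probes with consecutive identifier numbers changed together. Among the probes changed at least 2-fold, 11 consecutive pairs moved the same way, against a mean of 0.325 and a highest value of 4 over 10000 permutations of the probes (p = 1e-04, the smallest the permutations can give). Of the 31 risers 12 lay in such runs and of the 12 fallers 6, with a longest run of 4 in either direction. Across tested probes the sigC mean correlated at 0.270 between consecutive numbers and at 0.068 between numbers 5 apart, and the vector array at 0.170 between consecutive numbers. Position on the array is argued against, since adjacent spots with numbers more than 5 apart correlated at 0.00645. A candidate explanation is that the numbers follow gene order and that neighbouring genes were transcribed together; the 11 pairs cannot be told apart from other numbering schemes without a table of probe positions.

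Swapping before and after on 1 sigC array at a time gave at most 0 called probes, against 1194 for the real labels, so 1 of the 4 arrangements, the real one, reached that count. With 4 arrangements the share is never under 0.05. Any ratio that repeats across the sigC arrays, a dye preference included, would lose its call on such a swap. The swaps therefore do not tell the sources of the ratios apart. The control probes other than empty spots were dim to moderate: the brightest had a Cy5 signal 18.97 times that of empty spots on the vector array and 2.63 to 8.35 times on the sigC arrays.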
